A study of Mus musculus with 8 samples.

How the data were processed

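Total brain RNA of MOG-immunized mice was measured on Affymetrix whole-transcript arrays, 1 array for each of 8 samples. Per the labels' protocols, brain tissue was snap-frozen, RNA was purified with a column kit, and biotin-labelled cDNA was prepared with the WT Plus reagent kit. The labels give each sample's genotype and treatment, and 2 replicate numbers per group. The descriptions carry a different number for each sample, whose meaning the labels do not state. No source states that replicates were separate animals, so p-values measure the spread between these samples.

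The deposited table holds 33793 probe sets in 8 columns. Its values, taken as log2, are the authors' processed values. The labels do not state the log base, the summarisation, the between-array normalization or any row filter, and these steps are not given in the sources used here. Each row was found to be centred on its median over the 8 arrays (largest absolute row median 5e-07), so the table carries differences but no absolute levels. Base 2 is an assumption that the values support without proving, and every printed log2 difference and fold rests on it: the single-precision step left in them places the signal before centring at 4 to 8 for 25915 rows and at 8 or above for 7576, with 302 unresolved (tolerance 0.05 of a step), a range that log2 intensities of such arrays take. Column medians over all rows were -0.0037 and -0.0028 for wild-type PBS 1 and 2, -0.0016 and 0.014 for wild-type NDP-MSH, 0.0019 and -0.0043 for e/e PBS, and 0.0008 and 0.0007 for e/e NDP-MSH. The number of arrays limits the precision.

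Probe sets were named through the platform annotation given with the table: 23521 had 1 gene symbol, 1814 had several and were left out, and 8458 were unnamed here. Of the named ones 23328 had an Entrez identifier in the RefSeq gene table of assembly GRCm38.p6, each with the same symbol there. Probe sets of a gene were averaged (1082 genes had more than 1), which gave 22180 genes. The plan fixed before the data were examined took the brightest probe set of each gene and left out the dimmest 25%. Both steps need absolute levels, so the mean and no filter were used in their place.

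The tests used limma 3.58.1 in R 4.3.3: a linear model with 1 coefficient per group over all 8 arrays (4 residual degrees of freedom, prior degrees of freedom 3.45), moderated two-sided tests, and Benjamini-Hochberg adjustment over all genes at a threshold of 0.05. The 4 comparisons were NDP-MSH against PBS in each genotype, the difference of these effects, and e/e against wild-type under PBS. 40 gene lists were written before the data were examined and tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and fry, whose p tests whether a list moves 1 way on balance, were alternatives. On simulated data with genes that varied independently, camera with the estimated correlation missed a shift of -0.5 in a list of 17 genes (adjusted p = 0.654). The preset called this shift, which was set in the e/e comparison (adjusted p = 0.0057). Lists whose genes vary together were not simulated, so false calls of the preset in such lists were not checked.

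Genes named in the text followed a rule fixed before the data were examined. For each comparison they are the 8 largest rises and 8 largest falls past the threshold, filled up to 8 per direction by smallest p among genes whose groups do not overlap and that differ by at least 1.5-fold, which are stated as not past the threshold. From each list they are up to 2 rises and 2 falls past 0.05 over the list alone, or otherwise the 2 smallest p. The melanocortin receptors, Nr4a1 and the sex-linked genes are named always, and predicted, small RNA, receptor-family and clone symbols are not named by the first part.

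The gene test was checked on simulated data for the wild-type comparison over 22180 genes: it called 32% of genes changed by a log2 value of 0.5, 84% at 1, 98% at 2 and 98% at 3, and 8 of 21980 unchanged genes. In the e/e comparison, with no simulated change, it called 0 of 22180. Alternatives were the replicate number as a block, array weights, another quantile normalization, centring on array medians, only the 4 arrays compared, every row as its own feature, and leaving out each array. Robust moderation, only probe sets at a signal of 8 or above, and only genes with 1 probe set were added after seeing the data. The quantile normalization acted on row-centred values. It matched the spread of these values between arrays and not the signal levels, so it can shrink or stretch real differences. Slide, scan date and disease scores were not used here, so no batch could be tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.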

Results

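RNA from total brain was measured on 8 microarrays. The mice had been immunized with myelin oligodendrocyte glycoprotein (MOG) and were taken on day 14, when the labels place the maximum of the disease. MOG immunization of mice is a model of multiple sclerosis in which T cells attack central nervous myelin. The mice were wild-type, with a black coat, or C57BL/6Je/e (e/e below), with a yellow coat. The e/e allele inactivates Mc1r, the melanocortin receptor of pigment cells. Mice of each genotype received phosphate-buffered saline (PBS) or NDP-MSH, a long-lived analog of the hormone alpha-MSH that activates melanocortin receptors. NDP-MSH was given intravenously at 5 µg per mouse on days 8, 10 and 12. The 4 groups (wild-type PBS, wild-type NDP-MSH, e/e PBS and e/e NDP-MSH) held 2 arrays each. Values are taken as log2, since the base is not stated, and are centred gene by gene, so differences between arrays can be read and absolute levels cannot. Changes are given as log2 differences ± SE from the limma fit over all 8 arrays.

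Arrays of the same group differed in sex-linked and in regional transcripts. Xist, the transcript expressed from the inactive X chromosome of females, lay at 0.56 and 0.67 in wild-type PBS 1 and 2, at 0.62 and -0.56 in wild-type NDP-MSH 1 and 2, at 0.56 and -0.82 in e/e PBS 1 and 2, and at -4.46 and -4.56 in e/e NDP-MSH 1 and 2. The Y-linked gene Eif2s3y lay between -0.19 and 0.02 in the 4 wild-type arrays and e/e PBS 1, at 2.04 in e/e PBS 2, and at 2.78 and 2.87 in the e/e NDP-MSH arrays. Kdm5d and Uty, also Y-linked, followed Eif2s3y, with 2.07 and 2.32 in e/e PBS 2. e/e PBS 2 thus carried Xist and Y-linked signal together, and the e/e NDP-MSH arrays carried Y-linked signal with low Xist. Transcripts of the anterior pituitary were high in wild-type NDP-MSH 1 alone, where prolactin (Prl) lay at 6.97, growth hormone (Gh) at 6.54, Pomc at 3.64 and Cga at 2.31, against values between -0.47 and 0.29 for these 4 genes in the other arrays. The olfactory bulb transcript Cdhr1 lay at 2.23 in wild-type NDP-MSH 2 and at 0.49 or below in the other arrays. Prl, Gh, Cga and Cdhr1 belong to preset lists and were singled out after their values were seen.

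**Figure D1:**
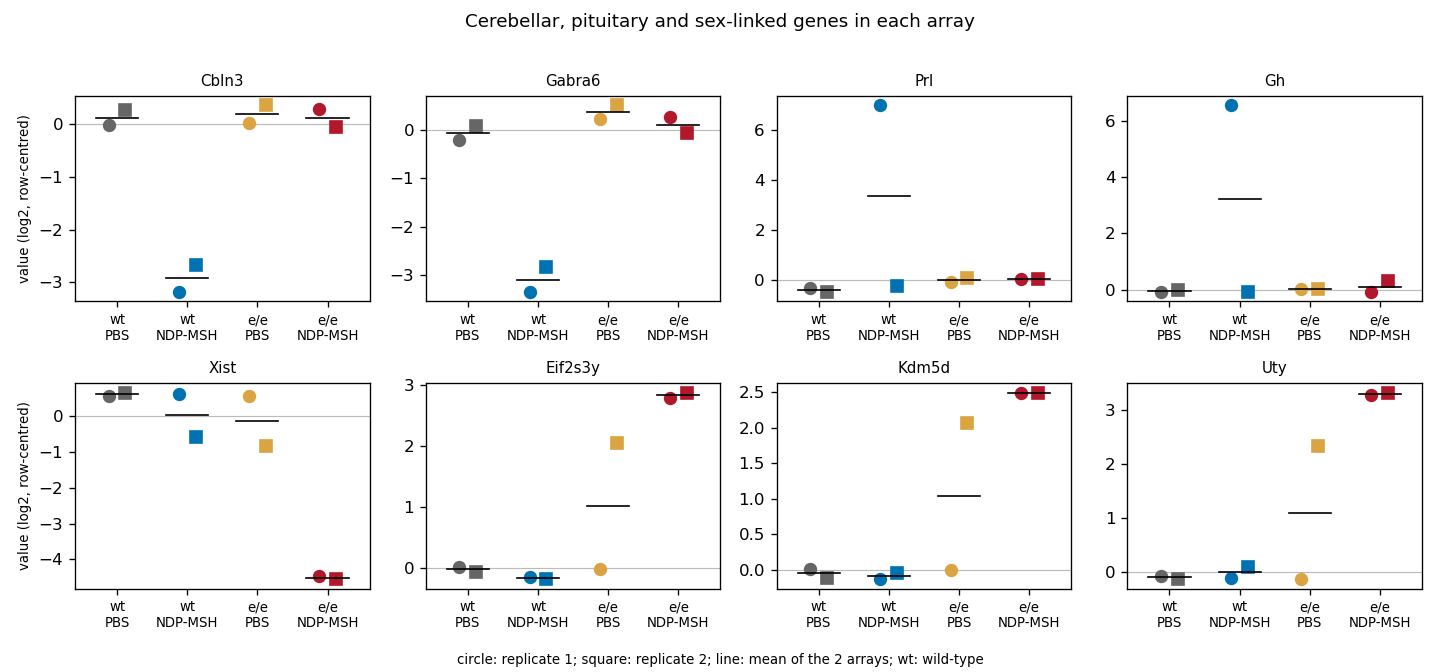
Values of 2 cerebellar genes (Cbln3, Gabra6), 2 pituitary genes (Prl, Gh) and 4 sex-linked genes in each array, on the vertical axis in log2 units centred on each row's median, by group on the horizontal axis, with a circle for replicate 1, a square for replicate 2 and a line at the mean. Cbln3 lay at -3.19 and -2.67 in the wild-type NDP-MSH arrays, Prl stood at 6.97 in wild-type NDP-MSH 1 alone, and Xist was lowest in the e/e NDP-MSH arrays.

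The first comparison that the series names asks how NDP-MSH changed brain transcripts in wild-type mice with a functional Mc1r. Transcripts of the cerebellum were lower after NDP-MSH in both arrays. Cbln3, a synapse organiser of cerebellar granule cells, fell by 3.05 ± 0.21 (limma, adjusted p = 0.00662), and Gabra6, the GABA receptor subunit of granule cells, fell by 3.02 ± 0.20. Car8 fell by 2.34 ± 0.17 and Ppp1r17 fell by 2.41 ± 0.29, and both mark Purkinje cells, the output neurons of the cerebellar cortex. Arhgef33 fell by 2.39 ± 0.16, Dao, the D-amino acid oxidase of cerebellar glia, fell by 1.96 ± 0.18, Cbln1 fell by 1.82 ± 0.16 and Zic1 fell by 1.61 ± 0.18. Zic1 lost its call in 8 of 16 alternative settings, Ppp1r17 in 7 of 16, Dao in 5 of 15 and Cbln1 in 4 of 16. Car8 lost it in 2 of 16, and Cbln3, Gabra6 and Arhgef33 in 1 of 16 each. None of these genes changed direction. In the preset cerebellum list, 12 of 12 genes were lower with a median of -1.14, 7 fell over all genes tested and 10 fell when adjusted over the list alone. The list passed camera (adjusted p = 2e-19), had an adjusted p = 0.517 with an estimated correlation, and passed fry (adjusted p = 0.0384). The list median lay at -1.26 and -1.03 in the wild-type NDP-MSH arrays and between -0.05 and 0.28 in the other 6.

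In wild-type mice, 39 of 22180 genes passed an adjusted p of 0.05, of which 38 fell and 1 rose. At a signal of 8 or above 67 genes passed, of which 61 fell and 6 rose. The rise among the 39 was Ifitm2, which encodes an interferon-induced membrane protein, at 1.02 ± 0.13 (adjusted p = 0.0428). Ifitm2 has close paralogs, and sharing of probes with them was not tested. It lost its call with the replicate block, array weights, another quantile normalization or only the 4 arrays compared, and without any 1 of the arrays other than the e/e PBS arrays. At an unadjusted p under 0.05, 2733 genes differed where chance gives 1109, of which 1490 were higher and 1243 lower. Of the 2733, 236 differed by at least 1.5-fold, 77 of them higher and 159 lower. Leaving out wild-type PBS 2 left 0 calls, wild-type NDP-MSH 1 left 7, wild-type NDP-MSH 2 left 11, wild-type PBS 1 left 15, and either e/e NDP-MSH array left 13. The cerebellum list kept its call without each array in turn, with a median between -1.35 and -0.92.

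Among genes that were higher without passing the threshold, those chosen by smallest p were Lyve1, a marker of lymphatic vessels and border macrophages, at 0.81 ± 0.12 (adjusted p = 0.0887), Cbr2 at 0.80 ± 0.13, Ifit1bl1 at 0.71 ± 0.12, Scnn1a, a subunit of the epithelial sodium channel, at 0.68 ± 0.11, Khdrbs3 at 0.68 ± 0.12, the desmosomal gene Pkp2 at 0.66 ± 0.10 and Lrg1 at 0.60 ± 0.10. Without either e/e PBS array Lyve1 passed (adjusted p = 0.0328) and so did Khdrbs3 (0.0469), which also passed at a signal of 8 or above (0.0334) and lay at 1.23 after another quantile normalization, short of the threshold (0.0585). Lrg1 and Selp (P-selectin, 1.16 ± 0.31), both of activated endothelium, rose when adjusted over their list alone, and Mcam fell by 0.47 ± 0.11. That list as a whole did not pass (camera adjusted p = 0.246).

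Genes of myelin and oligodendrocytes were lower in wild-type mice given NDP-MSH, in the same arrays in which the cerebellar genes were low. Of the list's genes 17 of 17 were lower, with a median of -0.29, 0 passed over all genes and 4 fell when adjusted over the list alone (camera adjusted p = 9.59e-10, and adjusted p = 0.517 with an estimated correlation). Among them Aspa, the aspartoacylase of oligodendrocytes, fell by 0.51 ± 0.11 and Mog, the immunizing antigen, fell by 0.45 ± 0.10. Of 15 astrocyte genes 12 were lower, with a median of -0.17 (camera adjusted p = 0.0131, and adjusted p = 0.553 with an estimated correlation). Without wild-type NDP-MSH 2 the astrocyte call ended (adjusted p = 0.096). No astrocyte gene passed over the list alone, and the smallest p values were those of Slc4a4 at -0.59 ± 0.15 and the water channel Aqp4 at -0.48 ± 0.14.

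The lists that were higher in wild-type mice given NDP-MSH were read from the same arrays, in which cerebellar genes were low, pituitary genes were high in array 1 and the olfactory gene Cdhr1 was high in array 2, and their values were not adjusted for this. Heat shock and unfolded protein response genes were higher, 22 of 23 with a median of 0.22. Of these 7 rose when adjusted over the list alone and 0 over all genes (camera adjusted p = 7.84e-07, and adjusted p = 0.517 with an estimated correlation). Sdf2l1, a chaperone of the endoplasmic reticulum, rose by 0.57 ± 0.14 and Creld2 by 0.46 ± 0.09 on that adjustment. In the hippocampus and cortex list 12 of 16 genes were higher, with a median of 0.38, and 3 rose over the list alone, among them the cortical transcription factor genes Fezf2 (0.75 ± 0.20) and Neurod6 (0.75 ± 0.18), the latter past the threshold over all genes without either e/e PBS array (adjusted p = 0.0469). Oxidative phosphorylation (39 of 44 higher, median 0.14), cell cycle (23 of 26, median 0.20) and cytosolic ribosomal protein genes (32 of 41, median 0.12) were also shifted up, with 0 members past either adjustment. The camera adjusted p of these last 4 lists was 0.0038, 0.000146, 0.000173 and 0.00562 in that order, and each had an adjusted p = 0.907 with an estimated correlation. The hippocampus and cortex call ended in 3 of 18 alternative settings, the estimated correlation and fry among them. The median of that list was 0.23 without wild-type NDP-MSH 2. Without that array the calls of oxidative phosphorylation (median 0.048, adjusted p = 0.149) and ribosomal protein genes (median 0.038, adjusted p = 0.316) ended, and the latter also ended without wild-type PBS 1 (0.152). The ribosomal protein median was 0.060 after another quantile normalization and 0.18 at a signal of 8 or above, past the threshold in both.

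Inflammatory gene lists did not pass in wild-type mice. Interferon gamma response genes had a median of 0.12 (13 of 17 higher, camera adjusted p = 0.608), type I interferon genes 0.18 (20 of 23 higher, adjusted p = 0.321), activated microglia and macrophage genes -0.13 (16 of 24 lower, adjusted p = 0.321), T cell genes 0.11 (adjusted p = 0.321) and MHC class II genes -0.24 (adjusted p = 0.449). Nr4a1, a nuclear receptor gene induced by cAMP signalling, differed by 0.12 ± 0.30, and on the immediate early list its relative Nr4a2 (0.51 ± 0.11) and the Fos family gene Fosl2 (0.46 ± 0.10) rose when adjusted over the list alone. Fosl2 lay at 0.71 after another quantile normalization. That list did not pass camera (adjusted p = 0.0678). Among the melanocortin receptors Mc5r lay at 0.47 ± 0.18 and Mc4r at 0.19 ± 0.08, neither past the threshold (adjusted p = 0.367 and 0.37), and Mc1r at -0.02 ± 0.09, Mc2r at 0.05 ± 0.08 and Mc3r at -0.06 ± 0.09.

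**Figure D2:**
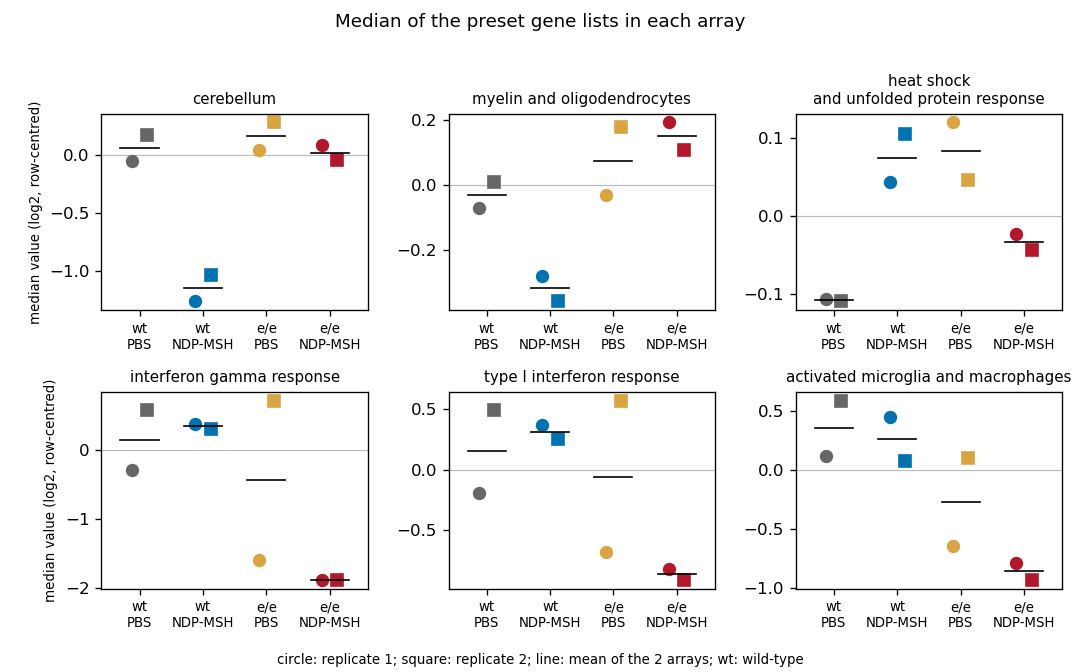
Median of 6 preset gene lists in each array, on the vertical axis in log2 units centred on each row's median, by group on the horizontal axis, with a circle for replicate 1, a square for replicate 2 and a line at the mean of both. The cerebellum list lay at -1.26 and -1.03 in the wild-type NDP-MSH arrays, and the interferon gamma list lay at -1.58 in e/e PBS 1, 0.70 in e/e PBS 2 and -1.87 in both e/e NDP-MSH arrays.

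The second comparison that the series names asks the same in e/e mice, which lack functional Mc1r. Interferon-induced and other inflammatory transcripts were lower after NDP-MSH as group means, but the 2 PBS arrays lay far apart. Both e/e NDP-MSH arrays carried Y-linked signal with low Xist, e/e PBS 1 had high Xist without Y-linked signal, and e/e PBS 2 carried both. A sex difference can therefore not be told apart from an NDP-MSH effect in this comparison. In the interferon gamma list 17 of 17 genes were lower, with a median of -1.42, and the list median lay at -1.58 in e/e PBS 1, 0.70 in e/e PBS 2 and -1.87 in both e/e NDP-MSH arrays. Type I interferon genes were lower in 23 of 23 (median -0.72), reactive astrocyte genes in 22 of 22 (median -0.46), activated microglia and macrophage genes in 23 of 24 (median -0.63), MHC class I genes in 13 of 13 (median -0.74) and MHC class II genes in 9 of 9 (median -0.25). These 6 lists passed camera, with adjusted p between 5.8e-16 and 3.56e-06, and each had an adjusted p = 0.288 with an estimated correlation. The MHC class I and class II calls ended when e/e PBS 2 was left out (medians -0.12 and -0.15, adjusted p = 0.123 and 0.1), and without e/e PBS 1 the medians were -1.38 and -0.49. The MHC class II median was -0.52 without e/e NDP-MSH 1. The other 4 lists stayed past the threshold with smaller medians, -0.28 for interferon gamma, -0.24 for activated microglia and macrophages, -0.20 for type I interferon and -0.097 for reactive astrocytes. Left out in its place, e/e PBS 1 gave medians of -2.55, -1.01, -1.24 and -0.79 for these 4. After another quantile normalization the medians were -0.82 for interferon gamma, -0.40 for activated microglia and macrophages and -0.46 for MHC class I, each past the threshold. The array with both Xist and Y-linked signal was e/e PBS 2.

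No gene passed an adjusted p of 0.05 in e/e mice by limma (0 of 22180, smallest adjusted p = 0.562), and 789 had an unadjusted p under 0.05, fewer than the 1109 that chance gives, with 395 higher and 394 lower. Of these 85 differed by at least 1.5-fold, 8 higher and 77 lower. After another quantile normalization 16 of 23 such genes were higher, so the direction of this split depended on that step. Without e/e PBS 1 the fit called 51 genes and without e/e PBS 2 it called 4, and the counts at 1.5-fold became 477 and 37. Without e/e PBS 2 the interferon gamma list median was -0.28, its camera call held (adjusted p = 0.000553), and 13 of the 40 lists passed in place of 21.

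The genes with the smallest p in e/e mice included the chemokine genes Ccl3 (-0.89 ± 0.17) and Ccl8 (-0.61 ± 0.16), the chitinase-like Chil3 of myeloid cells (-1.82 ± 0.45), Slc15a3 (-1.09 ± 0.29), Nckap1l of blood cells (-0.75 ± 0.20), Scgb3a1 (-0.67 ± 0.17) and Cpne7 (-0.66 ± 0.16). Ccl3 fell when adjusted over its list alone (limma, adjusted p = 0.0313), and 25 of 31 cytokine and chemokine genes were lower (median -0.33, camera adjusted p = 2.67e-08, and adjusted p = 0.288 with an estimated correlation), a call that ended without e/e PBS 2 (median -0.066, adjusted p = 0.0984), with a median of -0.83 without e/e PBS 1. Xist lay at -4.38 ± 0.48, Uty at 2.20 ± 0.64, Eif2s3y at 1.81 ± 0.54 and Kdm5d at 1.46 ± 0.54, so the sex-linked genes moved with the treatment groups. Without e/e PBS 1 and without e/e PBS 2 in turn, Xist lay at -3.69 and -5.07, Uty at 0.97 and 3.43, Eif2s3y at 0.78 and 2.84 and Kdm5d at 0.42 and 2.50, each past the threshold except Kdm5d without e/e PBS 1. Left out in the same way, these arrays moved Slc15a3 to -1.61 and -0.56, Nckap1l to -1.06 and -0.44, Dkkl1 to 1.09 and 0.36 and Slc5a7 to 0.96 and 0.22. Without e/e PBS 1, Slc15a3 passed the threshold (adjusted p = 0.0261), as did Ccl3 at -1.17 (0.0295). After another quantile normalization Xist lay at -2.37, Kdm5d at 0.68, Chil3 at -0.99, Slc15a3 at -0.71, Ccl3 at -0.59, Nckap1l at -0.45 and Dkkl1 at 1.09, none past the threshold. Higher genes without a call were Dkkl1 (0.72 ± 0.25), Tagap1 (0.68 ± 0.14), Sncg (0.59 ± 0.09) and Slc5a7, the choline transporter (0.59 ± 0.23). In the interferon gamma list the smallest p values were those of Cxcl10 (-2.26 ± 0.83) and Irgm2 (-1.83 ± 0.64), and in the MHC class II list that of H2-Ab1 (-2.55 ± 0.80), none past the list adjustment.

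Smaller shifts were seen in further lists of the e/e comparison, where sex was likewise not separated from treatment. Cell cycle genes were lower in 26 of 26 (median -0.14, camera adjusted p = 7.84e-08, and adjusted p = 0.303 with an estimated correlation). Heat shock and unfolded protein response genes were lower in 19 of 23 (median -0.13, adjusted p = 1.38e-09, and 0.288 with an estimated correlation), and Xbp1 (-0.39 ± 0.08) and Hspa5 (-0.37 ± 0.08) fell over the list alone. Cholesterol synthesis genes were higher in 16 of 17 (median 0.12, adjusted p = 0.000109, and 0.288 with an estimated correlation), with Srebf2 at 0.25 ± 0.08. The heat shock median was -0.071 without e/e PBS 1. The cell cycle median was -0.24 without e/e PBS 1, and its call ended without e/e PBS 2 (adjusted p = 0.699), and the cholesterol call without e/e PBS 1 (median 0.068, adjusted p = 0.225) or e/e NDP-MSH 1 (median 0.036, adjusted p = 0.14), with a median of 0.19 without e/e NDP-MSH 2. Cerebellar genes had a median of -0.10 in e/e mice (10 of 12 lower, adjusted p = 0.0261, and 0.654 with an estimated correlation), and that call ended without e/e PBS 2 or e/e NDP-MSH 2 (medians -0.037 and -0.06, adjusted p = 0.926 and 0.632). The cerebellar median was -0.25 without e/e PBS 1 and -0.17 without e/e NDP-MSH 1. Nr4a1 differed by -0.10 ± 0.30 and Mc1r by -0.01 ± 0.09. The array level of Mc1r says nothing about whether the receptor works.

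Whether the NDP-MSH effect differed between the genotypes was tested as the difference of effects, wild-type minus e/e. Y-linked signal was high in both e/e NDP-MSH arrays and in e/e PBS 2, and in no wild-type array. A sex difference between the e/e groups can therefore not be told apart from a genotype difference in this test. The cerebellum list had a median difference of -1.09, with 11 of 12 genes lower and 8 past over the list alone, and the myelin list -0.39, with 17 of 17 lower and 4 past over the list alone. Interferon gamma genes had a median difference of 1.55 (17 of 17 higher), type I interferon genes 0.84 (23 of 23) and heat shock and unfolded protein response genes 0.36 (22 of 23, 8 past over the list alone). Camera called 20 of 40 lists, 17 up and 3 down, and 0 with an estimated correlation, where the adjusted p of these 5 lists was 0.463, 0.463, 0.514, 0.551 and 0.463. The interferon gamma median difference was 0.35 without e/e PBS 2 and 2.75 without e/e PBS 1, and that of type I interferon 0.39 and 1.45. After another quantile normalization that of interferon gamma was 1.01. The myelin median difference was -0.26 without wild-type NDP-MSH 2. With each array left out in turn, these 5 lists stayed past the threshold.

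No gene passed for the difference of effects by limma (0 of 22180, smallest adjusted p = 0.126), and 1711 had an unadjusted p under 0.05 where chance gives 1109. The lowest adjusted p was shared by Cbln3 (-2.99 ± 0.29), Gabra6 (-2.76 ± 0.28) and Ebf1 (-1.29 ± 0.13). Other genes with small p were Car8 (-2.12 ± 0.24), Arhgef33 (-2.03 ± 0.23), Lhx1 (-1.19 ± 0.15), Kcng4 (-0.98 ± 0.12) and Pvalb (-0.93 ± 0.12) below 0, and Ifitm2 (1.60 ± 0.18), Lct (1.15 ± 0.19), Lrg1 (0.96 ± 0.14), Pkp2 (0.92 ± 0.14), St6galnac5 (0.77 ± 0.11), Creld2 (0.74 ± 0.12), Xbp1 (0.68 ± 0.11) and Kif23 (0.66 ± 0.10) above it. Single arrays moved the count: 7 genes passed without e/e PBS 1, 5 without wild-type NDP-MSH 2, 3 without e/e PBS 2 and 1 without wild-type NDP-MSH 1. Another quantile normalization gave 1, Car8 (-1.83, adjusted p = 0.0175), and a signal of 8 or above gave 11, among them Cbln3, Gabra6, Ebf1, Arhgef33, Car8, Kcng4 and Pvalb. Across genes the effects in the 2 genotypes had a Pearson r of 0.052 and a Spearman rho of 0.052, where genes are not independent replicates.

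Under PBS, e/e brains were compared with wild-type brains, a contrast the layout implies. The Y-linked median was 2.07 in e/e PBS 2, and 0.0051 and -0.11 in wild-type PBS 1 and 2. A sex difference can therefore contribute to this contrast and was not separated from genotype. Activated microglia and macrophage genes were lower in e/e in 24 of 24 (median -0.64), MHC class II genes in 9 of 9 (median -0.56), complement genes in 13 of 15 (median -0.55) and homeostatic microglia genes in 12 of 14 (median -0.29). Their camera adjusted p lay between 5.63e-13 and 2.4e-05, and with an estimated correlation the adjusted p was 0.578 for the first and 0.556 for the others. The sizes moved with single arrays: without e/e PBS 1 the medians were -0.23 for activated microglia and macrophages, -0.25 for MHC class II and -0.25 for complement, and without wild-type PBS 2 they were -0.31 for the first, -0.32 for complement and -0.14 for homeostatic microglia. The MHC class II median was -0.84 without wild-type PBS 1. The activated microglia list median lay at 0.12 in wild-type PBS 1, 0.59 in wild-type PBS 2, -0.64 in e/e PBS 1 and 0.10 in e/e PBS 2. Ms4a7 of macrophages fell by 0.65 ± 0.12 when adjusted over its list alone, and Adgre1, a macrophage marker, lay at -0.92 ± 0.18. Heat shock and unfolded protein response genes were higher in e/e in 21 of 23 (median 0.22, camera adjusted p = 5.63e-13, and 0.404 with an estimated correlation). Of these 7 rose over the list alone, among them Hspa5 (0.42 ± 0.08) and Hsph1 (0.46 ± 0.12), which lay at 0.32 without e/e PBS 1 and at 0.83 after another quantile normalization.

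No gene passed between the genotypes under PBS by limma (0 of 22180, smallest adjusted p = 0.839), and 1088 had an unadjusted p under 0.05 where chance gives 1109. The count was 4 without e/e PBS 1. Lower in e/e without a call were Etnppl (-0.96 ± 0.15), the lipid droplet gene Plin4 (-0.94 ± 0.20), Apoc2 (-0.82 ± 0.19), the cold-inducible Cirbp (-0.77 ± 0.13), Sfrp5 (-0.69 ± 0.10) and Wfdc17 (-0.60 ± 0.12). Higher were Gabra2 (1.04 ± 0.25), Fabp7 (0.90 ± 0.27), Chordc1 (0.75 ± 0.18), Wdfy1 (0.72 ± 0.22), H4c14 (0.67 ± 0.16), Fosl2 (0.63 ± 0.10), Myl6 (0.60 ± 0.19) and Lman2l (0.59 ± 0.10). Leaving out e/e PBS 1 moved H4c14 to 0.40, Chordc1 to 0.45 and Apoc2 to -0.49, and leaving out wild-type PBS 1 moved Gabra2 to 0.62 and Wdfy1 to 0.30, which lay at 1.13 without wild-type PBS 2. All 8 higher genes were larger after another quantile normalization. Fabp7 then lay at 2.00, Gabra2 at 1.98, Chordc1 at 1.63 and Wdfy1 at 1.41. H4c14 lay at 1.26, Myl6 at 1.14, Lman2l at 0.96 and Fosl2 at 0.96. None passed the threshold, so the sizes of these rises depended on that step. Fosl2 and Nr4a3 (0.58 ± 0.12) rose when adjusted over the immediate early list alone. T cell, MHC class I and reactive astrocyte genes were lower in e/e, with medians of -0.04, -0.41 and -0.21 and camera adjusted p of 0.0117, 0.00145 and 0.00228. Each had an adjusted p = 0.729 with an estimated correlation. When e/e PBS 1 was left out, their direction turned, to 0.0076 and 0.028 for the first pair without a call, and to 0.10 for reactive astrocytes, which passed as higher (adjusted p = 0.0188). When wild-type PBS 2 was left out, none of the 3 passed (adjusted p = 0.176, 0.551 and 0.0613).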

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

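The tests of explanations below were chosen after the patterns were seen, except that of the hindbrain Hox list, which was chosen before its values were seen. Each list in the next paragraph is given because the test of the difference of NDP-MSH effects between the genotypes, wild-type minus e/e, passed by camera at the preset correlation. None of the 20 passed with an estimated correlation or fry. The e/e groups also differed in sex-linked signal, so this test does not separate genotype from sex. Groups of 2 arrays are too small for a search for single outlying samples.

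Median log2 differences above 0 were 1.55 for interferon gamma response, 0.84 for type I interferon response, 0.62 for MHC class I presentation, 0.53 for reactive astrocytes, 0.44 for complement, 0.40 for cytokines and chemokines, 0.38 for monocytes and neutrophils, 0.38 for activated microglia and macrophages, 0.37 for cell cycle, 0.36 for heat shock and unfolded protein response, 0.31 for small nucleolar and spliceosomal RNAs, 0.27 for T cells, 0.26 for immediate early and cAMP-response genes, 0.24 for endothelial activation and adhesion, 0.19 for hippocampus and cortex, 0.13 for cytosolic ribosomal proteins and 0.086 for oxidative phosphorylation. Those below 0 were -1.09 for cerebellum, -0.39 for myelin and oligodendrocytes and -0.10 for astrocytes. Of the 22 reactive astrocyte genes 6 also stand on another list. The sizes moved with single arrays. Without e/e PBS 2 and without e/e PBS 1 in turn, the median was 0.35 and 2.75 for interferon gamma, 0.39 and 1.45 for type I interferon, 0.12 and 1.20 for MHC class I, 0.16 and 0.91 for reactive astrocytes, 0.14 and 0.64 for complement, 0.22 and 0.92 for cytokines, 0.017 and 0.79 for activated microglia, 0.23 and 0.50 for cell cycle and 0.42 and 0.089 for immediate early genes. Without wild-type NDP-MSH 1 and 2 in turn it was 0.20 and 0.60 for monocytes and neutrophils, 0.18 and -0.011 for oxidative phosphorylation and 0.22 and 0.064 for ribosomal proteins. After another quantile normalization it was 1.01 for interferon gamma, 0.41 for MHC class I and 0.22 for activated microglia and macrophages. The myelin median was -0.26 without wild-type NDP-MSH 2, that of astrocytes -0.17 without e/e NDP-MSH 2, and that of hippocampus and cortex ranged from 0.10 without wild-type PBS 2 to 0.52 without e/e PBS 2. Of the alternative settings, estimated correlation and fry included, 7 of 16 ended the complement call and 6 of 17 that of oxidative phosphorylation. Leaving out 1 array also ended some camera calls. For activated microglia and macrophages the adjusted p was 0.29 without wild-type PBS 1, 0.228 without wild-type NDP-MSH 1 and 0.556 without e/e PBS 2, and for MHC class I it was 0.135, 0.0593 and 0.556. For complement it was 0.205, 0.352 and 0.629, and 0.0815 without e/e NDP-MSH 2. Without wild-type NDP-MSH 1 the calls of T cells (0.111), monocytes and neutrophils (0.0879) and endothelial activation (0.0873) ended, and without e/e PBS 2 those of T cells (0.0998) and endothelial activation (0.0951). Astrocytes lost the call without wild-type NDP-MSH 2 (0.097), e/e PBS 2 (0.0529) or e/e NDP-MSH 1 (0.0832), and oxidative phosphorylation without wild-type NDP-MSH 2 (0.801), e/e PBS 1 (0.242) or e/e NDP-MSH 2 (0.193). Ribosomal protein genes lost it without wild-type NDP-MSH 2 (0.0938), and immediate early genes (0.106) and hippocampus and cortex (0.0763) without e/e PBS 1.

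Cerebellar genes were low in both wild-type NDP-MSH arrays and in no other array. The loss of a single cerebellar cell type as the whole cause is argued against by the granule cell and Purkinje cell lists. Their medians were -1.22 (11 of 11 lower) and -1.03 (7 of 7 lower). A shift or stretch of all values of an array is argued against by a cerebellum list median of -0.94 after another quantile normalization. That step matched centred values, so a distortion that depends on the signal level was not tested. Less cerebellar tissue in the RNA may account for the pattern, as 3 lists of cerebellar cells all had medians of -0.94 or lower. Of the 24 genes of these lists, 9 stand on the preset list. Others, Dao and Ppp1r17 among them, had themselves passed the threshold in wild-type mice, so the medians in part restate those calls. An action of NDP-MSH through the receptor that e/e mice lack was not excluded, as the cerebellum list median was -0.10 in e/e mice. Less cerebellar tissue in the wild-type NDP-MSH arrays alone would leave the same value in e/e mice, so it favours neither account. In wild-type NDP-MSH 1 and 2 the pituitary list median was 0.62 and -0.019, and the olfactory bulb list median was -0.0034 and 0.53. These values go with uneven tissue between the samples. None of them measures the cerebellar share, so the 2 accounts are not separated. Whether hindbrain tissue was missing too cannot be told apart from no such loss. The Hox list median was 0.0057, but 0 of its 15 genes reached a signal of 8. Glra1 and Slc6a5, picked afterwards, were both lower, at -0.95 ± 0.28 and -1.19 ± 0.20 (limma, unadjusted p = 0.0105 and 0.000425). Neither passed the threshold over all genes (limma, adjusted p = 0.285 and 0.115). Whether cerebellar cells also express these 2 genes was not tested, so they do not decide it.

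The interferon gamma list differed by 2.29 between the e/e PBS arrays. A shift or stretch of all values of an array is argued against by a gap of 1.79 after another quantile normalization. That step matched centred values, so a distortion that depends on the signal level was not tested. The idea that e/e PBS 2 is 1 of the wild-type samples measured here is argued against by Y-linked values 2.07 above the highest wild-type array. This does not test the genotype of e/e PBS 2. NDP-MSH lowering these genes in e/e mice cannot be told apart from differences between animals: e/e PBS 1 lay only 0.29 above the higher e/e NDP-MSH array and e/e PBS 2 lay far above it, so the size of the change rests on 1 array. Whether the values follow sex alone, with no effect of NDP-MSH, cannot be decided. e/e PBS 1, with Xist at 0.56 and a Y-linked median of -0.018, lay at -1.58. The e/e NDP-MSH arrays, with low Xist and Y-linked medians of 2.78 and 2.87, lay at -1.87. If animals of 1 sex did not vary, a mix of both sexes would lie between them, but e/e PBS 2 lay 2.29 above the highest of the 3. That value is the gap to be explained itself. A mix of sexes in e/e PBS 2 is not settled, and the spread between animals was not tested. No e/e PBS array had Y-linked signal with Xist as low as in the e/e NDP-MSH arrays, so a sex difference present only under PBS remains open and untested, as does the disease severity of each animal.

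In e/e PBS 2 Y-linked genes were high and Xist, at -0.82, lay between the e/e NDP-MSH arrays and the other arrays. RNA of a male alone is argued against by Xist, which lay 3.64 above the higher e/e NDP-MSH array. RNA of a male and a female in this array cannot be told apart from a low Xist of another origin: the share read from Xist (0.419) and that read from the Y-linked genes (0.531) added to 0.95, but wild-type NDP-MSH 2, without Y-linked signal, read as 0.508 from Xist and added to only 0.509. Whether the RNA was pooled on purpose is not stated in the labels.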

How the results depend on the processing

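Robust moderation, the signal of 8 or above and genes with 1 probe set were chosen after seeing the data. The filters of 25% and 50% and the intensity trend were not run because the centred values hold no levels. Genes past the threshold in wild-type mice were 39. They were 14 with the replicate block, 20 when quantile-normalized again, 5 with only the 4 arrays compared, 22 with every row of the table and 67 at a signal of 8 or above. Of the 39, the block kept 12 calls, the normalization 17, the 4 arrays 5, and the signal 30 of the 30 it measured, and all measured ones kept their direction in each setting run by gene. The cause was not tested, except that fewer arrays give fewer residual degrees of freedom. The samples share only a number: deviations of same-numbered arrays correlated across genes at -0.098 in the wild-type comparison, 0.179 in the e/e comparison and between -0.251 and 0.443 in the other pairs of groups. With the block the counts of the other comparisons stayed at 0.

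Counts at an unadjusted p under 0.05 and 1.5-fold were 421 with every row and 121 at a signal of 8 or above in wild-type mice (236), and 23 when quantile-normalized again (16 higher, against 8 of 85), 37 with only the 4 arrays and 18 at a signal of 8 or above in e/e mice (85). The difference of effects (0 genes) had 1 gene when quantile-normalized again and 11 at a signal of 8 or above, where 6513 genes were tested. Gene lists past the threshold were 8, 21, 20 and 14 in the wild-type, e/e, difference and PBS comparisons. They were 0 in each with an estimated correlation, and 1, 0, 0 and 0 with fry. At a signal of 8 or above, where lists hold fewer genes, they were 11 in e/e, 11 for the difference and 6 under PBS.

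Leaving out each array in turn, with a lone array assumed to vary like the other groups, gave 0 to 49 genes in the wild-type comparison, 0 to 51 in e/e, 0 to 7 for the difference and 0 to 4 under PBS. The counts at 1.5-fold were 193 to 559 and 37 to 477, and those of lists 9 to 12, 13 to 23, 15 to 23 and 11 to 20. The directions of the fit or of camera turned as follows, each short of the threshold unless a p is given. Nr4a1 in wild-type mice was -0.16 without wild-type PBS 2 (range -0.16 to 0.40), and in e/e mice 0.064 when quantile-normalized again, 0.35 without e/e PBS 1 and 0.13 without e/e NDP-MSH 2 (range -0.54 to 0.35). Mc1r was 0.083 in wild-type mice without wild-type NDP-MSH 1 (range -0.13 to 0.083) and 0.0098 in e/e mice without e/e PBS 2 (range -0.032 to 0.0098). In e/e mice without e/e PBS 1, the camera direction turned for myelin, with a median of 0.037 (range 0.033 to 0.19), and immediate early genes, with 0.026 (range -0.24 to 0.026). Under PBS without that array it turned for MHC class I, with 0.028 (range -0.95 to 0.028), T cells, with 0.0076 (range -0.18 to 0.0076), and reactive astrocytes, with 0.10 (range -0.62 to 0.10, camera adjusted p = 0.0188). The median alone changed sign, with the camera call ended, for myelin under PBS without e/e PBS 2 (-0.037), immediate early genes under PBS without e/e PBS 1 (-0.05) and the difference in oxidative phosphorylation without wild-type NDP-MSH 2 (-0.011). Of the other rechecks of named genes and lists, 1557 gene values and 895 list values kept direction and side, 39 and 186 lost the call, and 26 and 0 gained it. The signal over background of each probe set is unknown beyond its range, so dim genes cannot be set apart.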

Other observations

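Small nucleolar and spliceosomal RNAs were lower after NDP-MSH in e/e mice in 31 of 36 genes, with a median of -0.21 (camera adjusted p = 1.57e-09, and adjusted p = 0.288 with an estimated correlation), which was -0.13 without e/e PBS 1 and -0.32 without e/e PBS 2. As above, sex was not separated from treatment in the e/e comparison. In wild-type mice the list did not pass (median 0.08, adjusted p = 0.449), although Snord70 rose by 0.81 ± 0.14 and Snord53 fell by 0.67 ± 0.14 when adjusted over the list alone. Monocyte and neutrophil genes were lower in e/e in 17 of 20 (median -0.18, adjusted p = 7.3e-06, and 0.288 with an estimated correlation), with Lcn2 at -0.90 ± 0.29, and the median was -0.099 without e/e NDP-MSH 2. In wild-type mice Ly6g, a neutrophil surface gene, rose by 0.39 ± 0.07 over its list alone. The microglial genes Fcrls (0.89 ± 0.21) and Selplg (0.43 ± 0.13) had the smallest p of the homeostatic list in wild-type mice, and none of that list passed.

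Under PBS, striatal genes were lower in e/e mice in 10 of 11 (median -0.35, camera adjusted p = 0.000219, and adjusted p = 0.729 with an estimated correlation), among them Pde10a (-0.47 ± 0.17) and Rgs9 (-0.59 ± 0.30), neither past the list adjustment, and the call ended without wild-type PBS 1 (median -0.099, adjusted p = 0.703) or e/e PBS 2 (median -0.17, adjusted p = 0.199). The striatal median was -0.58 without wild-type PBS 2 and -0.52 without e/e PBS 1. For this and the following lists under PBS, sex was not separated from genotype. Glucocorticoid response genes were lower in 16 of 19 (median -0.11, adjusted p = 0.000219, and 0.556 with an estimated correlation), and Ddit4 fell by 0.50 ± 0.09 and Plin4 fell by 0.94 ± 0.20 over the list alone. That median was -0.058 without wild-type PBS 1, -0.20 without wild-type PBS 2 and -0.064 without e/e PBS 2. Myelin genes were higher in 14 of 17 (median 0.08, adjusted p = 0.00129, and 0.715 with an estimated correlation), and Ugt8a (0.50 ± 0.08) and Fa2h (0.40 ± 0.11), both of myelin lipid synthesis, rose over the list alone. The myelin median was 0.029 without wild-type PBS 1 and 0.21 without e/e PBS 1, and the call ended without e/e PBS 2 (median -0.04, adjusted p = 0.809). The transporter gene Abcb1a of the blood-brain barrier fell by 0.50 ± 0.08 over its list alone but did not pass over all genes, and the endothelial list did not pass (camera adjusted p = 0.164).

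The 2 arrays of a group differed least in e/e NDP-MSH, with an SD of 0.17 over genes of the difference between them and 12 genes apart by over 1 on the log2 scale. In wild-type PBS these values were 0.17 and 29, in wild-type NDP-MSH 0.22 and 45, and in e/e PBS 0.25 and 197. The first principal component held 40.0% of the variance and the second 27.0%. On the first, e/e PBS 1 lay at 15.0, near the e/e NDP-MSH arrays at 19.7 and 22.8, and e/e PBS 2 at -6.84, near wild-type PBS 1 at -4.53. On the second, e/e PBS 2 lay at -18.8, near wild-type PBS 2 at -16.3 and away from wild-type PBS 1 at -4.2.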
